A study of Homo sapiens with 9 samples.

How the data were processed

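RNA-seq was available for 9 samples of the HCCLM3 cell line in 3 groups of 3, as given by the labels: DMSO control, quercetin 50 µM and quercetin 100 µM. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was bound to oligo(dT) beads and fragmented, and libraries were amplified by PCR and treated with duplex-specific nuclease, which lowers abundant transcripts. The nuclease step can compress differences in abundance between genes, and the bead step favours RNA with a poly(A) tail. The protocol text speaks of tissue although the samples are cells. The strand setting of the counting is not given in the sources used here.

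The authors deposited 1 table with 17492 genes. It holds expected counts (estimated counts of reads per gene), deposited by the authors without normalisation, 1 column per library. Per the submitters' processing notes the tools were HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 on the build GRCh38.p13, with their roles not given. Of the deposited counts 26.84% were whole within 1e-06. The authors also deposited FPKM and TPM per library, and log2 fold changes with p-values and q-values of their own comparisons; per the file headers the p-values and q-values came from DESeq2. The FPKM served as an alternative. The TPM and the normalised read counts were not used here. Gene symbols, identifiers and positions are those in the authors' table, 1-based on GRCh38; genes placed on other sequences than chromosomes are given without a position. The authors' hallmark set membership per gene was used in the closing section.

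Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10, a minimum total of 15 and a share of 0.7, which kept 12832 genes and removed 4660 genes holding 0.042% of the counts. Totals per library ran from 20061136 to 21599805 counts. Counts were scaled by TMM, and all 9 libraries entered 1 fit with a term for each group, so that the groups share an estimate of the spread. The common dispersion was 0.0206, a biological coefficient of variation of 14.4%, and the median standard error of a log2 fold change was 0.134. Genes were tested with edgeR's quasi-likelihood F test (robust, two-sided; edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The standard error is the absolute log2 fold change divided by the square root of F. 36 gene lists were written down in advance, and the 33 with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. With an estimated correlation 0 of 11 lists held at 50 µM, 3 of 14 at 100 µM (HIF targets, glycolysis and NRF2 targets) and 5 of 19 between the doses (those 3, the IGF axis, and epithelial-mesenchymal transition). The HIF and glycolysis lists share members, among them ALDOC, PGK1, LDHA and SLC2A1, so their results are not independent. The list of epithelial-mesenchymal transition holds epithelial genes such as CDH1, EPCAM and KRT8 beside mesenchymal ones such as VIM and ZEB1. Its direction therefore gives no direction of a transition. In the report a gene rises or falls only where it passed the test, and the counts adjusted over the list alone use the same threshold.

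Genes were named by a fixed rule. IGFBP3 was always named. In each comparison the rule then took the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, with a mean of at least 5 CPM and no overlap between the groups. From the 8 lists with the largest share of members past the threshold it took up to 3 members each, and it added all called genes of the IGF axis and the most abundant marker of each other cell type. Results of some genes that the rule names are not reported here. The groups, the fit, the lists, this rule and all alternatives except 2 were chosen before the data were examined. Nothing in the overlap of calls between doses is independent of the shared controls, so 50 sets of unchanged groups were simulated against them.

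The tests were tested on simulated data drawn from the real means, library sizes and gene-wise dispersions, with genes changed 1.5-fold or 2-fold. For 50 µM against control, run on 12739 genes, edgeR recovered 43.4% of 99 genes changed 1.5-fold and 79% of 100 changed 2-fold, and called 4 unchanged genes. For 100 µM against control, on 12732 genes, it recovered 35% of 100 and 72.7% of 99, and called 5 unchanged genes. For 100 against 50 µM, on 12713 genes, it recovered 33% and 76% of 100 each, and called 4 unchanged genes. The raised list was called in each simulation and 0 of 33 other lists were. The simulated genes were drawn independently of each other, so this 0 gives no rate of false calls for lists whose genes vary together. In the data at 50 µM the estimated correlation was 0.841 for ribosomal proteins and 0.584 for G1/S and DNA replication.

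Of 74 named genes, all found in GENCODE release 29, 18 have exons that overlap another protein-coding gene and 28 have exons that overlap a gene on the opposite strand. Among the genes named in the text these include CLDN2 with RIPPLY1, CA9 with ARHGEF39, CP with HPS3, CRYAB with HSPB2, CYP1B1 with RMDN2, NDUFA4L2 with SHMT2, TF with SRPRB, IGF2 with INS-IGF2, TAGLN with PCSK7, SLC16A6 with ARSG, FADS2 with FADS1 and FEN1, SREBF1 with RAI1, SLC16A3 with CSNK1D, TGFB1 with HNRNPUL1, NOP16 with ARL10 and HIGD2A, and WDR12 with CARF. Their counts are uncertain, since without strand the reads of such pairs cannot be told apart. The histone genes and the AKR1B and AKR1C genes have near-identical copies and are uncertain for that reason. IGFBP3 overlaps no other gene.

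The alternatives were RLE and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, a minimum log2 fold change of 1, a test against 1.5-fold, an adjusted p under 0.01, limma-trend on log2(FPKM + 1), each library left out in turn, and for lists an estimated correlation and fry. Both libraries that stand apart left out together, and limma's voom with quality weights, were added after the data were seen. No other scaling moved the median log2 fold change of all genes by more than 0.0351.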

Results

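RNA was sequenced from 9 samples of HCCLM3, an established human hepatocellular carcinoma line with a high metastatic potential. The series asks how quercetin, a plant flavonol, acts on hepatocellular carcinoma, and its title names IGFBP3, a secreted protein that binds insulin-like growth factors. The cells received the vehicle DMSO (control, 3 samples), quercetin at 50 µM (3 samples) or quercetin at 100 µM (3 samples). The length of treatment is not given in the sources used here. Control replicates 1, 2 and 3 held 21164948, 21436328 and 20061136 estimated counts. The libraries at 50 µM held 20762544, 21166114 and 21334167, and those at 100 µM held 21269069, 21599805 and 20890833. Of the 17492 genes in the table, 12832 passed the filter on low counts and were tested. Levels are given as normalised read counts (CPM, scaled by TMM), mean ± SD with n = 3 libraries per group. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

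A pair of libraries stood apart from their groups. Control replicate 1 differed from the other 2 controls with a chi-square of 27.6 and 27.4 per gene, against 3.56 between those 2. For 100 µM replicate 3 the values were 83.9 and 86.1, against 5.04 between the other 2 libraries of its group. The 3 libraries at 50 µM differed by 4.24 to 4.75, and no library was a copy of another. Both libraries are kept in the results. With both left out, an alternative added after the data were seen that lowers the measured spread, 3677 genes were higher and 3721 lower at 50 µM than in the control, 3125 and 3147 at 100 µM, and 3176 and 2929 at 100 than at 50 µM. These held 99.9%, 99.1% and 99.6% of the genes called with all 9 libraries, 0 of them in the opposite direction in edgeR.

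**Figure D1:**
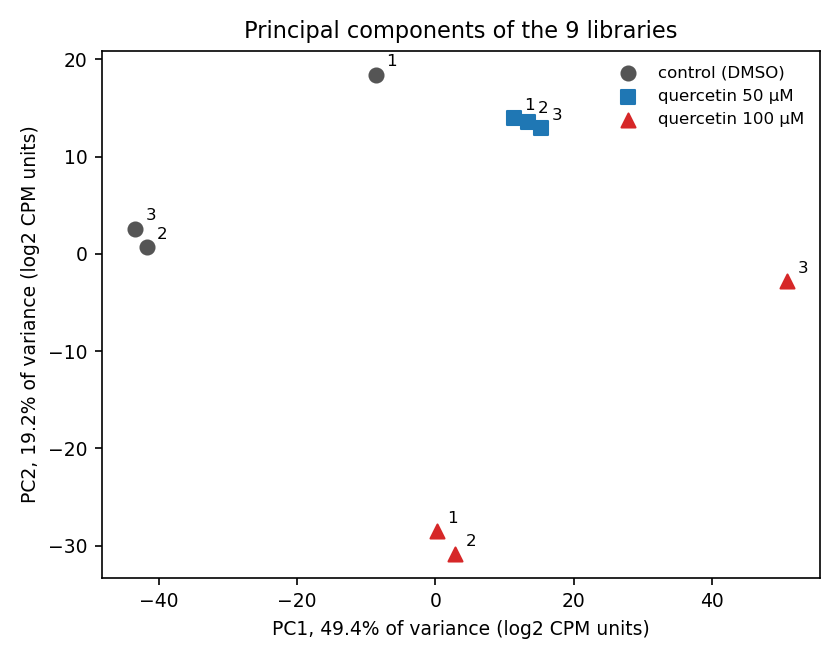
Principal components 1 and 2 of log2 CPM for the 9 libraries, in log2 CPM units, with the share of variance on each axis and the replicate number beside each point. Control replicate 1 lies at -8.61 on the first component against -41.8 and -43.5 for the other controls, and 100 µM replicate 3 lies at 50.9 against 0.17 and 2.88 for the other 100 µM libraries.

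IGFBP3 (gene 3486, GRCh38 chromosome 7, 45912245 to 45921272, minus strand) was higher at 100 µM than in the control. Its level was 8.92 ± 1.14 CPM in the control, 15.8 ± 2.52 at 50 µM and 177 ± 210 at 100 µM. The single libraries at 100 µM held 55.8, 55.4 and 419.9 CPM, so the mean of that group rests mainly on replicate 3. Against control the log2 fold change was 4.31 ± 0.775 (SE), with an adjusted p of 0.00567 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without 100 µM replicate 3 it was 2.65, with an edgeR adjusted p of 4.86e-07. At 50 µM all 3 libraries lay above all 3 controls, but the log2 fold change of 0.83 ± 0.736 did not pass the test (edgeR adjusted p = 0.455). That call depended on the spread lent by 100 µM replicate 3: without it the edgeR adjusted p was 0.00115, and in a fit of the 2 groups alone it was 0.00487. Between the doses IGFBP3 was higher at 100 µM by 3.48 ± 0.737 on the log2 scale (edgeR adjusted p = 0.0348), and by 1.81 without 100 µM replicate 3 (edgeR adjusted p = 1.37e-05). This last call was lost without control replicate 2 (edgeR adjusted p = 0.0629), control replicate 3 (0.0637) or 50 µM replicate 1 (0.147), 2 (0.143) or 3 (0.156). In the authors' deposited table the log2 fold changes of IGFBP3 were 0.82 at 50 µM (q = 4.06e-05), 4.31 at 100 µM (q = 0.00018) and 3.48 between the doses (q = 0.00732).

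**Figure D2:**
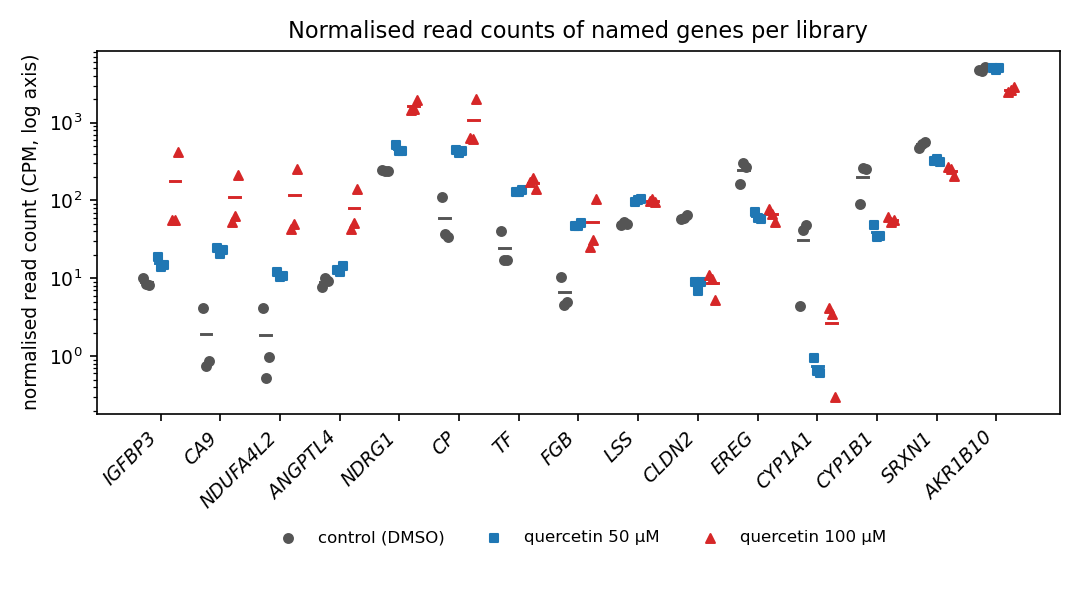
Normalised read counts (CPM, log axis) of 15 named genes in each library, as grey circles for control, blue squares for 50 µM and red triangles for 100 µM, with a bar at each group's mean. IGFBP3 lies at 55.4 to 419.9 CPM in the 100 µM libraries, while CLDN2 falls from a control mean of 61.1 to 8.31 and 8.6 CPM.

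Quercetin at 50 µM lowered CLDN2, which encodes a pore-forming tight junction protein, and the cytochrome P450 genes CYP1A1 and CYP1B1, which oxidise aromatic hydrocarbons. CLDN2 (gene 9075, chromosome X, 106900164 to 106930861) fell 7.35-fold, from 61.1 ± 3.59 to 8.31 ± 1.2 CPM (edgeR adjusted p = 0.000824). CYP1A1 (gene 1543, chromosome 15, 74719542 to 74725528) fell 42.3-fold, from 31.5 ± 23.6 to 0.738 ± 0.193 CPM (edgeR adjusted p = 0.0155), and CYP1B1 fell 5.18-fold to 38.9 ± 7.71 CPM (edgeR adjusted p = 0.00685). EREG, a ligand of the EGF receptor, fell 3.91-fold to 62.5 ± 6.61 CPM. The transporter gene SLC16A6 fell 8.05-fold and TAGLN, an actin-binding protein, 4.27-fold. Some genes of liver secretory proteins rose, while the 19 tested hepatocyte markers as a list did not pass, with 4 higher and 3 lower and, adjusted over the list alone, 7 and 4 (camera adjusted p = 0.301). The copper-carrying ferroxidase CP (gene 1356, chromosome 3, 149162410 to 149222008) rose 7.1-fold to 427.9 ± 16.5 CPM (edgeR adjusted p = 0.0184). Transferrin, TF, rose 5.26-fold to 130.7 ± 4.79 CPM, FGB, a fibrinogen chain, 7.26-fold to 48.4 ± 2.63 CPM, and ALB, serum albumin, 7.05-fold to 8.83 ± 2.37 CPM. SPTSSB, a subunit of the enzyme that starts sphingolipid synthesis, rose 5.35-fold. Without control replicate 1 the increases of CP, ALB and SPTSSB were 12.2-fold, 10.6-fold and 8.11-fold.

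Some lipid synthesis genes rose at 50 µM. Of 25 genes of cholesterol biosynthesis 10 rose and none fell (median log2 fold change 0.42, camera adjusted p = 1.45e-10, adjusted p = 0.577 with an estimated correlation). Adjusted over the list alone 13 rose. The sterol enzyme LSS rose 1.98-fold to 100.9 ± 4.3 CPM and FDFT1, which makes squalene, 1.79-fold to 470.1 ± 14.5 CPM. Of 21 genes of fatty acid synthesis and lipid storage 7 rose and none fell, 9 when adjusted over the list alone (median 0.29, camera adjusted p = 5.63e-07, adjusted p = 0.197 with an estimated correlation). The desaturases FADS2 and SCD rose 2.42-fold and 2.44-fold, to 942.1 ± 27.7 and 2375 ± 91.6 CPM, and the regulator SREBF1 rose 2.32-fold.

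Of 27 targets of the hypoxia-inducible factors (HIF) 9 rose at 50 µM, none fell and 18 did not pass, while 11 rose and 2 fell adjusted over the list alone (median 0.41, camera adjusted p = 0.000124, adjusted p = 0.577 with an estimated correlation). CA9, a carbonic anhydrase of the cell surface, rose 11.4-fold from 1.94 ± 1.96 to 22.6 ± 2.17 CPM (27.9-fold without control replicate 1), NDRG1 1.91-fold to 460.8 ± 51.1 CPM, and the aldolase ALDOC 2.66-fold. Of 20 glycolysis genes 7 rose, 8 adjusted over the list alone, among them PFKL (1.52-fold) and the lactate exporter SLC16A3 (1.79-fold). The list passed with camera adjusted p = 0.0134 and had adjusted p = 0.577 with an estimated correlation. Of 54 nuclear genes of oxidative phosphorylation 12 rose and 1 fell (camera adjusted p = 0.000124, adjusted p = 0.577 with an estimated correlation), and 19 rose and 2 fell adjusted over the list alone. Among 51 genes of G2/M and mitosis 12 rose and 1 fell, 15 and 1 adjusted over the list alone (median 0.11, camera adjusted p = 0.0134, adjusted p = 0.577 with an estimated correlation). The 74 cytosolic ribosomal protein genes had a median of 0.31 (camera adjusted p = 1.49e-07, adjusted p = 0.65 with an estimated correlation), although 0 passed singly in edgeR, also adjusted over the list alone. Of these 26 were higher at an unadjusted p under 0.05 and 9 in DESeq2.

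4 lists passed in the lower direction at 50 µM. Of 15 targets of the aryl hydrocarbon receptor (AhR) 4 fell and none rose, with CYP1A1, CYP1B1 and EREG among them (median -0.49, camera adjusted p = 0.00334, adjusted p = 0.577 with an estimated correlation); adjusted over the list alone 8 fell and 2 rose. Of 20 heat shock proteins 8 fell, including the co-chaperone BAG3 (1.68-fold, to 82 ± 2.25 CPM) and HSPA4L (1.7-fold, to 31.1 ± 3.65 CPM), while the small heat shock protein CRYAB rose 4.51-fold to 10.7 ± 1.26 CPM (median -0.28, camera adjusted p = 0.000562, adjusted p = 0.577 with an estimated correlation). Adjusted over the list alone 12 fell and 2 rose. Of 29 genes of autophagy and the lysosome 6 fell and 1 rose, 11 and 1 adjusted over the list alone (median -0.38, camera adjusted p = 0.000272, adjusted p = 0.577 with an estimated correlation). Of 39 genes of ribosome biogenesis and MYC targets 4 fell, the same count adjusted over the list alone (median -0.18, camera adjusted p = 0.00879, adjusted p = 0.577 with an estimated correlation). The list of epithelial-mesenchymal transition and invasion did not pass (camera adjusted p = 0.453): 6 of its 31 tested genes rose and 6 fell, 6 and 9 adjusted over the list alone, with the protease MMP7 higher 3.66-fold, the transcription factor SNAI2 lower 2.55-fold and the tight junction gene CLDN1 lower 2.14-fold. Within the IGF axis, IGFBP2 rose 2.88-fold to 59.1 ± 3.73 CPM and the insulin receptor INSR fell 1.67-fold to 18.4 ± 0.772 CPM, with 16 of 18 genes not past the threshold; adjusted over the list alone 3 rose and 4 fell (camera adjusted p = 0.965).

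In all, 678 genes were higher and 810 lower at 50 µM (1488 of 12832, 11.6%), 102 and 136 of them by at least 2-fold. The groups did not overlap for 6285 genes, 49% against 10% by chance. Left out 1 at a time, control replicates 2 and 3 gave 49 and 57 higher genes with 55 and 60 lower, and the 50 µM replicates 1, 2 and 3 gave 73, 95 and 47 higher with 64, 75 and 43 lower. Without control replicate 1 there were 1405 higher and 1437 lower, and without 100 µM replicate 3, 2382 and 2357. Of the 31 named genes past the threshold, 16 lost the call without control replicate 2, 15 without control replicate 3, and 13, 13 and 17 without 50 µM replicates 1, 2 and 3. Those never lost included CLDN2, EREG, SPTSSB, TF, NDRG1, FDFT1, LSS, FADS2, SCD, CRYAB, HSPA4L, IGFBP2 and PECAM1. All 31 passed without both libraries that stand apart, but 99.9% of all calls at 50 µM return in that setting. The return of the named genes there is therefore no further check of them. Without control replicate 1 the calls of glycolysis (median 0.11 against 0.14 with all libraries, camera adjusted p = 0.129) and of G2/M and mitosis (0.14 against 0.11, 0.078) were lost. The latter was also lost without 50 µM replicate 1 (0.1, 0.0757) and in a fit of the 2 groups alone (0.11, 0.0674). Calls were gained without control replicate 1 by YAP/TEAD targets (median -0.42, camera adjusted p = 0.0146), immediate early genes (-0.17; 0.0389) and hepatocyte markers (0.44; 0.0363, and 0.000144 without both libraries that stand apart), without control replicate 3 by fibroblast markers (-0.5; 0.0181), and without 50 µM replicate 3 by YAP/TEAD targets (-0.31; 0.0384) and fibroblast markers (-0.58; 0.0384).

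At 100 µM most of the tested HIF targets rose. Of 27 tested targets 20 rose and none fell, with a median 2.42-fold increase, and 23 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.73e-31, adjusted p = 0.0442 with an estimated correlation). CA9 (gene 768, chromosome 9, 35673809 to 35681159) rose 55.5-fold to 109.7 ± 88.9 CPM (edgeR adjusted p = 0.00121). NDRG1 (gene 10397, chromosome 8, 133237171 to 133297304) rose 6.73-fold, from 241.4 ± 6.06 to 1624 ± 268 CPM (edgeR adjusted p = 1.38e-05). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 8.79-fold to 79.1 ± 54.8 CPM. NDUFA4L2, a mitochondrial protein named for its likeness to a respiratory chain subunit, rose 61.1-fold to 116.2 ± 121 CPM (gene 56901, chromosome 12, 57234903 to 57240762; edgeR adjusted p = 0.00258). Leaving out 100 µM replicate 3, CA9, NDUFA4L2 and ANGPTL4 were 29.6-fold, 24.4-fold and 5.32-fold higher than in the control, and without control replicate 1 CA9 and NDUFA4L2 were 135.2-fold and 157-fold higher. 8 of 20 glycolysis genes rose and 1 fell, 10 and 1 adjusted over the list alone (camera adjusted p = 1.49e-09, adjusted p = 0.0442 with an estimated correlation). Some of them, such as ALDOC, PGK1 and LDHA, are also in the list of HIF targets, so the lists are not separate findings.

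**Figure D3:**
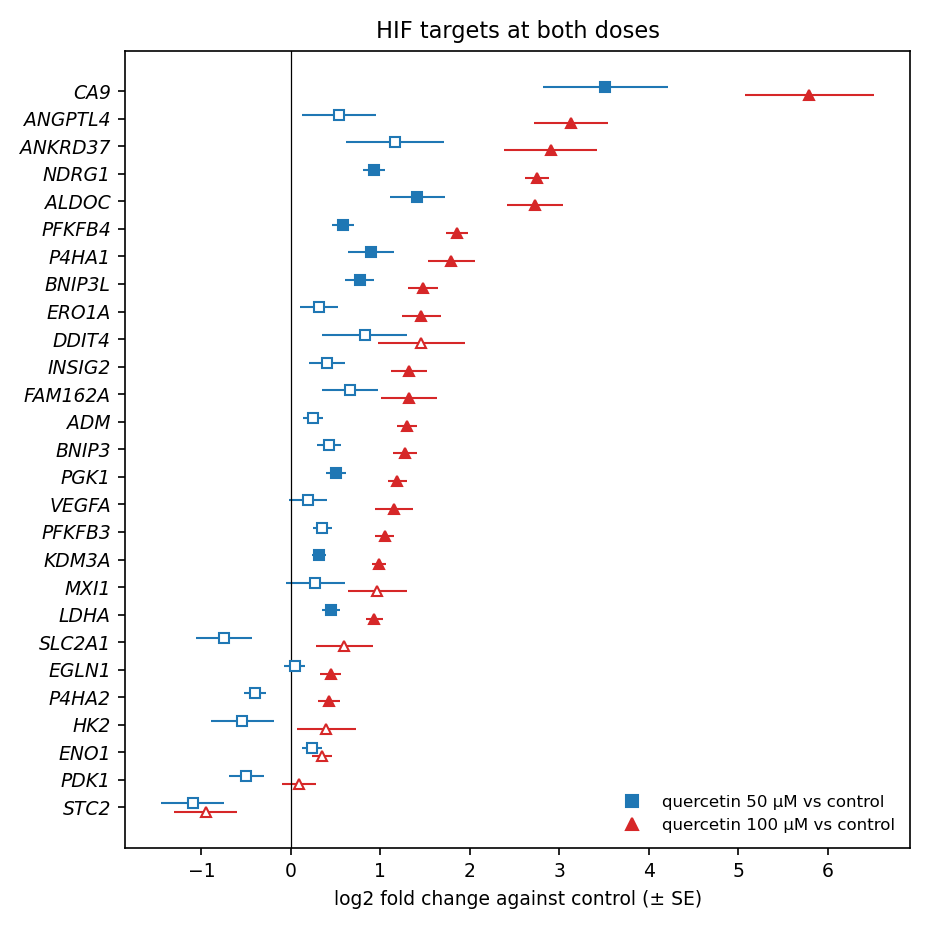
Log2 fold change against control (± SE) of the 27 tested HIF targets at 50 µM (blue squares) and 100 µM (red triangles), with filled symbols for genes past the threshold in edgeR. At 100 µM 20 targets are past it, all higher, against 9 at 50 µM.

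The same 4 genes of liver secretory proteins were higher at 100 µM. CP rose 18.1-fold to 1093 ± 820 CPM (edgeR adjusted p = 0.00233), TF 6.78-fold to 168.8 ± 28.4 CPM, FGB 7.99-fold to 53.3 ± 43.5 CPM and ALB 8.34-fold to 10.5 ± 5.04 CPM. CP rose 10.3-fold and FGB 4.25-fold without 100 µM replicate 3, and without control replicate 1 CP rose 31-fold and ALB 12.5-fold. The 19 tested hepatocyte markers as a list did not pass, with 7 higher and 4 lower and, adjusted over the list alone, 8 and 4 (camera adjusted p = 0.507). Without both libraries that stand apart the list passed (median 0.093, camera adjusted p = 0.00105). Of the IGF axis 6 of 18 genes rose and none fell, the same counts adjusted over the list alone (median 0.32, camera adjusted p = 0.0218, adjusted p = 0.168 with an estimated correlation). Besides IGFBP3 these were IGFBP2 (2.54-fold), the growth factor IGF2 (7.52-fold, to 3.01 ± 0.394 CPM), IRS1 (1.26-fold), TMEM219, which encodes a receptor of IGFBP3 (1.36-fold, edgeR adjusted p = 0.0497), and IGFBP5. IGFBP5 and LGI4, a secreted protein of the nervous system, rested on 100 µM replicate 3: their log2 fold changes of 7.23 and 5.2 became 3.27 and 3.22 without it, at edgeR adjusted p of 0.022 and 8.52e-05. IGFBP5 stood at 0.776, 0 and 0 CPM in the controls, so its fold has no measured denominator, and the call was lost without control replicate 1, 2 or 3. TMEM219 lost the call without control replicate 2 or 3, any of the 50 µM libraries, or 100 µM replicate 2 or 3, with log2 fold changes of 0.29 to 0.58 over all 9 omissions. The median of the IGF axis was 0.18 without control replicate 3, and IGF2 was 15-fold higher without control replicate 1.

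NRF2 targets, which encode enzymes of the oxidative stress response, were lower as a list at 100 µM: 13 of 27 fell and none rose, 17 and 0 adjusted over the list alone (median -0.34, camera adjusted p = 1.07e-07, adjusted p = 0.0366 with an estimated correlation). The aldo-keto reductase AKR1B10 (gene 57016, chromosome 7, 134527567 to 134543083) fell 1.81-fold, from 4799 ± 311 to 2658 ± 195 CPM (edgeR adjusted p = 0.000549). Sulfiredoxin, SRXN1, fell 2.16-fold to 242.7 ± 32.5 CPM and the cystine transporter SLC7A11 1.69-fold to 281.5 ± 44.3 CPM. Of 39 genes of ribosome biogenesis and MYC targets 25 fell and none rose, 34 fell adjusted over the list alone (median -0.42, camera adjusted p = 1.95e-14, adjusted p = 0.0978 with an estimated correlation). The RNA polymerase I subunit POLR1B fell 1.83-fold, the ribosome assembly factor RRS1 1.9-fold and UTP20 1.78-fold. Of 51 genes of G1/S and DNA replication 10 fell and none rose, 20 fell adjusted over the list alone (median -0.35, camera adjusted p = 1.17e-07, adjusted p = 0.496 with an estimated correlation), with a median of -0.18 without 100 µM replicate 3. Of 20 heat shock proteins 12 fell and 1 rose, 15 and 1 adjusted over the list alone (camera adjusted p = 2.08e-06, adjusted p = 0.22 with an estimated correlation). FKBP4 and HSPA4L fell 1.69-fold and 1.94-fold, and CRYAB rose 4.68-fold.

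Most of the tested replication-dependent histone genes rose at 100 µM, 13 of 19 past the threshold and none lower, 16 adjusted over the list alone (median 1.21, camera adjusted p = 2.79e-09, adjusted p = 0.191 with an estimated correlation). H2BC4 (gene 8347, chromosome 6, 26113170 to 26123926) rose 3.12-fold from 6.83 ± 1.83 to 21.3 ± 1 CPM, H2BC5 3.94-fold and H4C8 7.25-fold. H4C8 had a log2 fold change of 2.86, and 1.84 without 100 µM replicate 3. These messengers mostly lack poly(A) tails and have near-identical copies, so their counts in libraries made with oligo(dT) beads are uncertain. Cholesterol biosynthesis (13 of 25 higher, 1 lower; 15 and 1 adjusted over the list alone) and fatty acid synthesis (9 of 21 higher, 1 lower; 14 and 1 adjusted over the list alone) passed again, with camera adjusted p of 4.14e-09 and 1.5e-06, and adjusted p = 0.233 and adjusted p = 0.0595 with an estimated correlation. The cholesterol median of 0.5 was 0.32 without 100 µM replicate 3. LSS rose 1.95-fold to 99.4 ± 5.08 CPM and the mevalonate pathway gene MVD 1.91-fold to 65.1 ± 11.2 CPM.

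CLDN2 fell 7.09-fold at 100 µM, to 8.6 ± 2.97 CPM (edgeR adjusted p = 0.000165), and EREG 3.7-fold, CYP1B1 3.56-fold and CYP1A1 11.7-fold. ENPP2, which makes lysophosphatidic acid, fell 3.92-fold, and RAB7B, a GTPase of late endosomes, 3.46-fold. The AhR targets did not pass as a list (camera adjusted p = 0.0929), with 6 of 15 lower and 2 higher, 8 and 3 adjusted over the list alone; NEDD9, a scaffold protein of cell adhesion, was among the higher (3.69-fold). Without control replicate 1 the AhR targets passed (median -0.45, camera adjusted p = 0.000185), as they did in a fit of the 2 groups alone (0.035). Genes of autophagy and the lysosome (3 higher and 6 lower of 29, camera adjusted p = 0.19) passed without control replicate 1 (0.00867), and integrated stress response genes (3 higher and 7 lower of 28; 0.137) without control replicate 3 (0.0229). 24 genes of the NF-kB and inflammatory list had a median of 0.7, with 8 higher and none lower, also adjusted over the list alone (camera adjusted p = 0.00229, adjusted p = 0.514 with an estimated correlation). Without 100 µM replicate 3 the median was 0.21 and the call was lost (camera adjusted p = 0.0904). The 74 ribosomal proteins (3 higher, 0 adjusted over the list alone; median 0.29, camera adjusted p = 8.08e-05, adjusted p = 0.8 with an estimated correlation) had a median of 0.036 without that library, and the call was lost (camera adjusted p = 0.408). TGF-beta and SMAD targets (8 of 23 higher, none lower; 11 and 1 adjusted over the list alone) and the list of epithelial-mesenchymal transition (9 of 31 higher, 2 lower; 9 and 4 adjusted over the list alone) passed at camera adjusted p of 0.0173 and 0.0196, and had adjusted p = 0.182 and adjusted p = 0.168 with an estimated correlation. The latter had a median of 0.12, of 0.21 without 100 µM replicate 1 and of 0.2 without replicate 2, and lost the call without control replicate 1 (median 0.14, camera adjusted p = 0.0787).

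In all, 1370 genes were higher and 1322 lower at 100 µM (2692, 21%), 391 and 85 of them by at least 2-fold. The groups did not overlap for 4613 genes, 35.9% against 10% by chance. Without control replicate 2 there were 622 higher and 496 lower, without control replicate 3, 598 and 457, and without 50 µM replicate 1, 1030 and 871. A fit of the 2 groups alone gave 587 and 437. Of the 39 named genes past the threshold 34 kept the call whichever single library was left out; the others were IGFBP5, TMEM219, CYP1A1 (lost without control replicate 2 or 3, or 100 µM replicate 3), IRS1 (control replicate 2 or 3) and CD68 (control replicate 2, or 100 µM replicate 1 or 2), with log2 fold changes of -3.02 to -4.06, 0.28 to 0.39 and 0.46 to 0.73 over the 9 omissions.

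**Figure D4:**
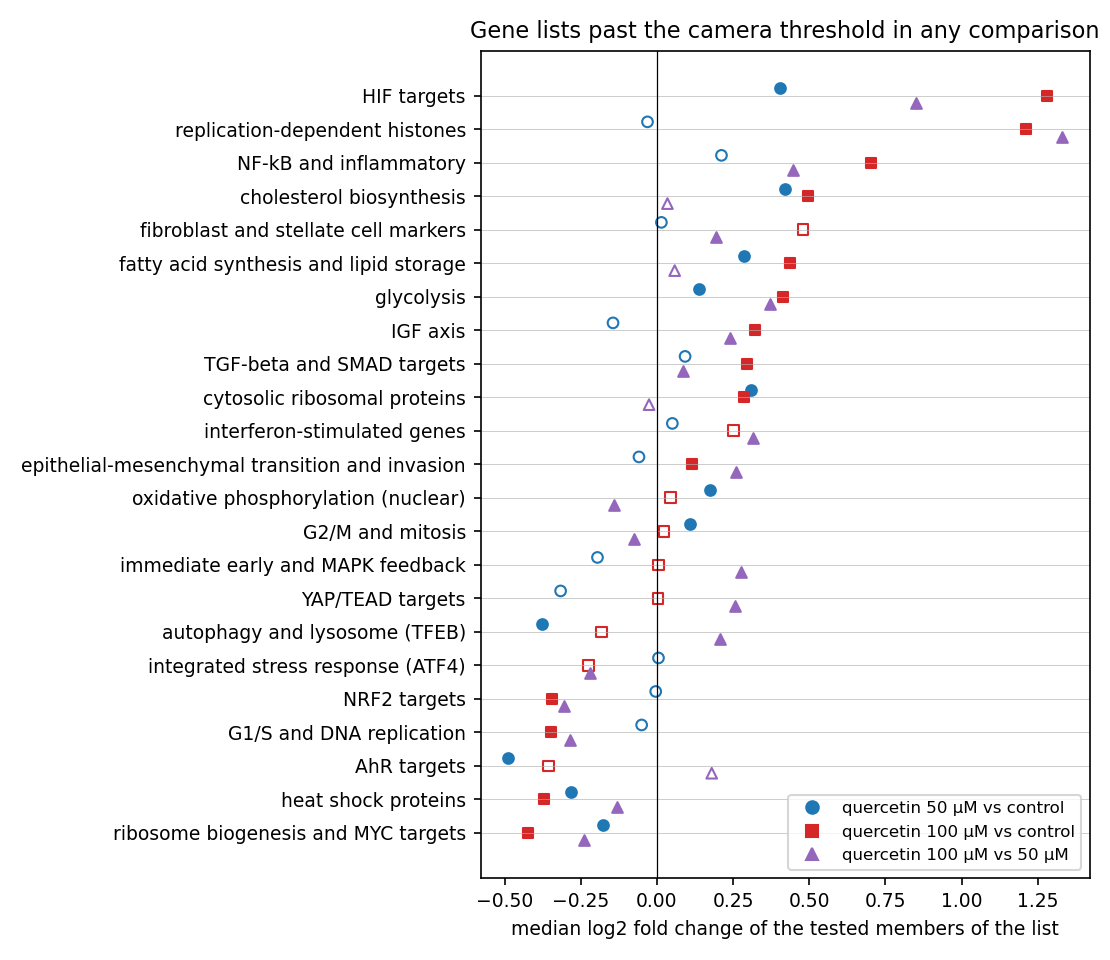
Median log2 fold change of the tested members of each gene list that passed the camera threshold in any comparison, with filled symbols where it passed, for 50 µM against control (circles), 100 µM against control (squares) and 100 against 50 µM (triangles). HIF targets have the highest median at 100 µM, 1.28, and genes of ribosome biogenesis and MYC targets the lowest, -0.42.

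The direct comparison of the doses asks which genes differ between 100 and 50 µM. HIF targets were higher at 100 µM, 16 of 27 with none lower, 22 adjusted over the list alone (median 0.85, camera adjusted p = 8.24e-32, adjusted p = 0.0317 with an estimated correlation). NDRG1 was 3.53-fold higher (edgeR adjusted p = 0.000325), ANGPTL4 6.05-fold (edgeR adjusted p = 0.012), NDUFA4L2 10.4-fold (edgeR adjusted p = 0.039) and the glucose transporter SLC2A1 2.54-fold (edgeR adjusted p = 0.0484). SLC2A1 passed against control at neither dose, with log2 fold changes of -0.746 at 50 µM and 0.5994 at 100 µM (edgeR adjusted p = 0.138 and 0.197). ANGPTL4 was 3.64-fold and NDUFA4L2 4.12-fold higher without 100 µM replicate 3. Of 20 glycolysis genes 6 were higher and 1 lower, 12 and 2 adjusted over the list alone (camera adjusted p = 5.59e-08, adjusted p = 0.0417 with an estimated correlation), with the enolase ENO2 2.42-fold and ALDOC 2.49-fold higher. NRF2 targets were lower, 8 of 27 with none higher, 15 and 1 adjusted over the list alone (median -0.3, camera adjusted p = 3.45e-11, adjusted p = 0.00986 with an estimated correlation). AKR1B10 was 1.85-fold lower (edgeR adjusted p = 0.0023), AKR1C1 1.57-fold, from 3224 ± 113 to 2056 ± 87.4 CPM, and SLC7A11 1.42-fold.

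The IGF axis had 3 of 18 genes higher and none lower at 100 than at 50 µM, 5 adjusted over the list alone (median 0.24, and 0.45 without 100 µM replicate 3, camera adjusted p = 0.000544, adjusted p = 0.0417 with an estimated correlation). IGFBP1, another binding protein of the growth factors, was 4.2-fold higher (41.7 ± 4.45 against 174.9 ± 87.1 CPM) and INSR 1.65-fold. The list of epithelial-mesenchymal transition had 4 of 31 genes higher, 9 adjusted over the list alone, and none lower (camera adjusted p = 1.83e-06, adjusted p = 0.0317 with an estimated correlation). That list mixes epithelial and mesenchymal genes, so this result does not show a transition in either direction. The growth factor TGFB1 was 1.74-fold higher (160.5 ± 13.1 CPM), in a list of TGF-beta targets with 6 of 23 higher, 8 adjusted over the list alone (camera adjusted p = 0.00329, adjusted p = 0.0986 with an estimated correlation). The call of that list was lost without both libraries that stand apart (median 0.053, camera adjusted p = 0.285) and with voom quality weights (0.043, 0.285). Histone genes were higher, 8 of 19, 15 adjusted over the list alone (camera adjusted p = 1.49e-16, adjusted p = 0.0822 with an estimated correlation), with H2BC4 3.51-fold, H2BC5 2.6-fold and H4C8 5.18-fold. Immediate early genes were higher, 5 of 31 against 1 lower, 8 and 2 adjusted over the list alone (median 0.28, and 0.17 without 100 µM replicate 2, camera adjusted p = 0.0026, adjusted p = 0.265 with an estimated correlation), among them the phosphatase gene DUSP1 (2.37-fold), KLF6 (1.72-fold) and IER3 (1.43-fold). TMEM45A was 4.52-fold higher and the proteoglycan gene DCN 3.38-fold. Higher at 100 than at 50 µM did not always mean above the control. Against control the median of immediate early genes was -0.195 at 50 µM and 0.00441 at 100 µM (camera adjusted p = 0.0688 and 0.799). IER3 held 67.93 to 69.57 CPM in the controls, 45.95 to 50.25 at 50 µM and 63.03 to 72.19 at 100 µM. INSR held 26.2 to 32.9, 17.9 to 19.3 and 26.4 to 32.9 CPM. DUSP1 was above all controls at both doses.

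Genes of ribosome biogenesis and MYC targets were lower at 100 than at 50 µM, 9 of 39 and 23 adjusted over the list alone (camera adjusted p = 3.34e-13, adjusted p = 0.0822 with an estimated correlation), with BOP1 1.45-fold, NOP16 1.42-fold and WDR12 1.51-fold lower. Genes of G1/S and DNA replication (4 of 51 lower, 9 adjusted over the list alone, camera adjusted p = 7.39e-11, adjusted p = 0.426 with an estimated correlation) had a median of -0.28, and of -0.1 without 100 µM replicate 3. Oxidative phosphorylation genes (1 of 54 lower, 0 adjusted over the list alone in edgeR, camera adjusted p = 1.7e-05, adjusted p = 0.426 with an estimated correlation) had a median of -0.14, of -0.093 without 50 µM replicate 3 and of -0.077 without 100 µM replicate 1. Against control their median was 0.175 at 50 µM and 0.0454 at 100 µM, where the list did not pass (camera adjusted p = 0.799). Lower between the doses thus did not mean below the control for this list. The transcription factor genes CEBPA, which acts in liver differentiation, and FOXQ1 were 1.73-fold and 1.71-fold lower, and SPAAR, a small regulatory polypeptide, and UFSP1 1.95-fold and 1.71-fold. ABCA4, a lipid transporter, was 1.83-fold lower, at 80.6 ± 3.8 against 147.8 ± 3.69 CPM (edgeR adjusted p = 0.00407).

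Another 8 lists passed between the doses, and with an estimated correlation none of them did. Higher at 100 µM were NF-kB and inflammatory genes (camera adjusted p = 0.00159, then adjusted p = 0.472 with an estimated correlation), interferon-stimulated genes (0.0112, then 0.0822), genes of autophagy and the lysosome (0.0155, then 0.619), YAP/TEAD targets (0.0138, then 0.437) and fibroblast and stellate cell markers (0.013, then 0.0987). Their higher and lower genes numbered 1 and 0 of 24, 1 and 0 of 23, 0 and 0 of 29, 2 and 0 of 21, and 1 and 0 of 5; adjusted over the list alone they numbered 5 and 0, 2 and 1, 0 and 0, 3 and 1, and 2 and 0. Lower were heat shock proteins (0.0293, then 0.536), integrated stress response genes (0.0293, then 0.437) and genes of G2/M and mitosis (0.0207, then 0.536), with 0 and 1 of 20, 2 and 2 of 28, and 0 and 1 of 51; adjusted over the list alone 0 and 1, 3 and 6, and 0 and 1. Without 100 µM replicate 3 the calls of NF-kB (median 0.45, then 0.055, camera adjusted p = 0.314) and fibroblast markers (0.2, then -0.16, 0.347) were lost. So were those of heat shock proteins (-0.13, then -0.12, 0.345), the integrated stress response (-0.22, then -0.31, 0.345) and G2/M (-0.076, then -0.082, 0.304), whose medians were about as large or larger without that library. The medians of TGF-beta targets (0.087) and lysosome genes (0.21) became 0.043 and 0.32. Calls were also lost for YAP/TEAD targets without 100 µM replicate 1 (median 0.15, camera adjusted p = 0.0571), for lysosome genes without 100 µM replicate 1 (0.19, 0.146) or 2 (0.14, 0.139), for the integrated stress response and fibroblast markers without 50 µM replicate 2 (medians -0.14 and 0.12, camera adjusted p = 0.135 and 0.0951), and for heat shock and G2/M genes without 50 µM replicate 1 (medians -0.091 and -0.059, camera adjusted p = 0.056 and 0.158). The fibroblast median was 0.34 and 0.33 without 100 µM replicates 1 and 2. Against control the median of YAP/TEAD targets was -0.316 at 50 µM and 0.00388 at 100 µM, and that of lysosome genes -0.376 and -0.181. The median of G2/M genes against control was 0.108 at 50 µM and 0.0232 at 100 µM, where that list did not pass (camera adjusted p = 0.747). The medians of the NF-kB, interferon and fibroblast lists against control were positive at both doses. At 50 µM, however, the mean log2 fold changes of the interferon and fibroblast lists were -0.0536 and -0.267. The direction of the camera test was down for both there (camera adjusted p = 0.892 and 0.0688). Among lysosome genes 7 were higher and 1 lower in edgeR at an unadjusted p under 0.05, and 2 were higher in DESeq2. Ribosomal protein genes did not pass between the doses (median -0.026, camera adjusted p = 0.43), but were lower without 100 µM replicate 3 (median -0.26, camera adjusted p = 7.03e-11). Cholesterol biosynthesis and fatty acid synthesis did not pass between the doses (camera adjusted p = 0.838 and 0.675).

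In all, 289 genes were higher and 243 lower at 100 than at 50 µM (532, 4.15%), 78 and 1 of them by at least 2-fold. The groups did not overlap for 3559 genes, 27.7% against 10% by chance. Left out 1 at a time, the 50 µM replicates 1, 2 and 3 left 31, 41 and 31 higher and 12, 26 and 12 lower, control replicates 2 and 3 left 152 and 159 higher and 77 and 89 lower, and 100 µM replicates 1 and 2 left 127 and 120 higher and 50 and 46 lower. Without 100 µM replicate 3 there were 1823 and 1738, and without control replicate 1, 446 and 363. A fit of the 2 groups alone gave 180 higher and 71 lower, and limma on log2 FPKM gave 380 lower and a share of 39.5% higher, against 54.3% here. Of the 31 named genes past the threshold 21 or 22 lost the call without one of the 50 µM libraries, 15 and 14 without control replicates 2 and 3, and 10 and 11 without 100 µM replicates 1 and 2. Those never lost were ABCA4, CEBPA, SPAAR, AKR1B10, NDRG1, AKR1C1, DCN, ENO2 and H2BC4. Without 100 µM replicate 3 the log2 fold changes of NDUFA4L2 (3.38), TMEM45A (2.18), H4C8 (2.37), ALDOC (1.32) and H2BC5 (1.38) were 2.04, 1.31, 1.34, 0.8 and 0.87.

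At both doses 907 genes passed in the same direction, 440 higher and 467 lower, among them CLDN2, CP, TF, NDRG1 and LSS. Independent lists of these sizes would share 156, and 50 simulations of unchanged groups against the same 3 controls shared 0 in edgeR. Unchanged groups pass the threshold for few genes, so that 0 was fixed in advance and gives no scale for the 907. The log2 fold changes at the doses correlated across 12832 genes, which are not independent replicates, with r = 0.71 against 0.502 in the simulations. Their covariance was 0.182 against a simulated 0.032, a difference of 0.15. The 3 controls could not be divided into 2 sets of at least 2 libraries, so part of the excess may come from the shared controls. Of the 1784 genes past at 100 µM and not at 50 µM, 333 also passed between the doses, and of the 580 past at 50 µM and not at 100 µM, 65 did. Left out 1 at a time, control replicates 1, 2 and 3 gave 1751, 88 and 96 shared genes, the 50 µM replicates 122, 150 and 84, and 100 µM replicate 3 gave 1897, with 4075 without both libraries that stand apart. Among the 907 shared genes, those past the threshold between the doses were 47 further from the control at 100 µM and 2 nearer to it.

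Some markers of other cell types were measured. CD68 (191 CPM over all 9 libraries), LUM (91.9 CPM) and PECAM1 (22.1 CPM) led the lists of immune, fibroblast and endothelial markers, while PTPRC and COL1A1 stood at 0.706 and 0.31 CPM. CD68, a lysosomal membrane protein, was 1.51-fold higher at 100 µM than in the control (edgeR adjusted p = 0.0237) and 1.94-fold higher than at 50 µM (edgeR adjusted p = 0.013). PECAM1 fell 1.74-fold at 50 µM and 1.71-fold at 100 µM, from 30.7 ± 1.2 to 17.6 ± 1.22 and 18 ± 0.888 CPM. LUM did not pass in any comparison, with log2 fold changes of 0.015, 0.18 and 0.16, where the values for 100 µM were -0.19 and -0.21 without 100 µM replicate 3. Immune markers (5 tested) did not pass in any comparison. The endothelial list (4 tested), the erythroid list and the mitochondrially encoded messengers (0 tested each) were too small for the list test. The remaining lists passed in no comparison with all 9 libraries and the filter on low counts: the ER unfolded protein response, p53 targets, apoptosis regulators, fatty acid oxidation, metallothioneins, iron metabolism, WNT targets, and xenobiotic conjugation, with camera adjusted p of 0.129, 0.982, 0.152, 0.799, 0.914, 0.914, 0.752 and 0.914 at 100 µM. Without that filter the ER unfolded protein response passed, lower, at 50 µM (median -0.15, camera adjusted p = 0.0283) and 100 µM (-0.11, 0.0421). Apoptosis regulators passed, higher, at 100 µM without both libraries that stand apart (0.24, 0.0306) and with voom quality weights (0.24, 0.0494). Median, mean and test direction differed in sign for 9, 4 and 4 lists in the 3 comparisons, 0 of them past the camera threshold.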

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

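The tests of mixture, exchange and a wrong label for 100 µM replicate 3, of a state shared between the libraries that stand apart, of mixture with 100 µM replicate 3, and of the HIF targets' median without both libraries that stand apart were chosen only after the result was seen.

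ABCA4 was past the threshold in opposite directions at the doses. Its log2 fold change was 0.5 ± 0.106 at 50 µM and -0.38 ± 0.107 at 100 µM (edgeR adjusted p = 0.0208 and 0.0338), and the direct comparison gave -0.87 ± 0.107 (edgeR adjusted p = 0.00407). The levels were 122.6, 90.5 and 101.2 CPM in the controls, 143.6, 149.9 and 150.1 at 50 µM, and 84.9, 77.7 and 79.2 at 100 µM. It was the 1 gene of this kind among the 12832 tested in the fit of all 9 libraries, and the count in other settings is not given here. By level alone TGFB1 also lay in opposite directions without overlap. It held 102 to 132 CPM in the controls, 85.75 to 97.25 at 50 µM and 149.3 to 175 at 100 µM.

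100 µM replicate 3 stood apart from its group. It had 204 genes more than 2-fold outside the range of the other 8 libraries, 174 above and 30 below, where the next library had 30, which argues against a mixture of these libraries. On 670 genes at least 2-fold apart between control replicates 2 and 3 (place 0) and the other libraries at 100 µM (place 1), its median place was 1.2 (quartiles 0.793 and 1.68), which argues against an exchange with a control. An exchange with a 50 µM library needs a partner out of place there, but those libraries differed from each other by a chi-square of at most 4.746 per gene, against at least 40.9 from the other 100 µM libraries. A 50 µM library under a wrong label, as the whole cause, would match that group, but the lowest chi-square against it was 61.34. A 50 µM library under a wrong label that also has a deviation of its own cannot be told apart from a 100 µM library with these samples: over 327 genes the median place from 50 µM (0) to the other 100 µM libraries (1) was 0.301, with quartiles of -0.262 and 0.795 on both sides of the middle. A trend on transcript length took away -1.39% of its median absolute deviation (0.312 before, 0.316 after), which argues against a loss of RNA by length. Its deviations correlated across genes with those of control replicate 1 at r = 0.533, with no library used in both. On the 670 genes control replicate 1 lay toward the other 100 µM libraries, at a median place of 0.421 (quartiles 0.146 and 0.751). Both libraries thus deviated partly along the difference between control and 100 µM, which alone could make their deviations correlate. Whether it does was not tested. A state of the culture or its handling shared by these libraries may be involved, and what it was is open.

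Control replicate 1 stood apart in the direction of the treated libraries for part of its genes, such as CP, TF and CA9 higher and CYP1A1 and CYP1B1 lower. A mixture with a 50 µM library would give 1 mixing fraction for all genes, but over 29 genes the fraction had an interquartile range of 0.363. For a mixture with 100 µM replicate 3 the median fraction was 0.573 over the genes lower in that library and 0.0985 over those higher in it, a gap of 0.475, which a single fraction does not allow. A denser culture was read from YAP/TEAD targets, whose median deviation was -0.415 in 100 µM replicate 3 and -0.24 in control replicate 1. These lay at percentiles 0.04 and 0.06 of 10000 random lists. The value in control replicate 1 missed the bound set in advance. A denser culture may be part of any state shared by these libraries and cannot be told apart from other causes with these samples.

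The rise of HIF targets at 100 µM was weighed against 3 explanations. Without both libraries that stand apart the median of all 27 tested targets was 1.04, as a difference of mean log2 CPM. It lay above the medians of 10000 random lists, so those libraries account for at most part of the rise. With them the median of the edgeR log2 fold changes was 1.28. These are different estimates, so the gap between them does not measure the part due to those libraries. No other scaling moved the median of all genes by more than 0.0292 in that comparison. Each scaling tried aligns the bulk of the genes, so that median could hardly move and the test cannot decide on a shift of all genes. Iron withdrawn from the cells, which would stabilise the messenger of the transferrin receptor TFRC, was argued against by a TFRC fold of 0.969 (95% interval 0.84 to 1.12). That reading rests on TFRC alone and cannot decide on a loss of iron that leaves its messenger unchanged. A response of these cells to quercetin may explain the rise, as a hypothesis; lower oxygen in those cultures was not tested and stays open.

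For each comparison the 6 libraries make 10 splits into 3 and 3, which cannot give a share under 0.05. The real split was the 1 of 10 with as many genes past the threshold, with 1488, 2692 and 532 genes in the fit of all 9 libraries, and the highest count in edgeR among the other splits was 0.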

How the results depend on the processing

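The settings that leave out both libraries that stand apart, and the tests with voom quality weights, were chosen only after the result was seen.

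Scaling by RLE or upper-quartile factors and a filter of 1 CPM in 3 libraries kept every count within 1.5 times and the 3 IGFBP3 results on their side of the threshold. Over all alternatives the named genes kept direction and call in 1876 cases, lost the call in 404, gained it in 4 and reversed in 2; for the lists the numbers were 1835, 99, 40 and, in camera, none reversed. The reversals were LUM at 100 µM against control (-0.36, edgeR adjusted p = 0.000264) and against 50 µM (-0.20, 0.0165), with both libraries that stand apart left out. The cause of the changes below was not tested, except that fewer libraries, a stricter threshold or a lower measured spread change the number of calls by construction. DESeq2 gave no adjusted p for IGFBP3.

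Counts follow as higher and lower genes for 50 µM against control, 100 µM against control and 100 against 50 µM, then genes called at both doses. With all 9 libraries they were 678 and 810, 1370 and 1322, 289 and 243, and 907. DESeq2 gave 1190 and 1341 for the first, 670 and 682 for the last comparison, and 1478 at both doses. Fitting only the 2 groups gave 1996 and 2273, 587 and 437, and 180 and 71. A log2 fold change of at least 1 left 102 and 136, 391 and 85, 78 and 1, and 133. The test against 1.5-fold left 15 and 13, 115 and 30, 12 and 0 in edgeR, and 18. An adjusted p under 0.01 left 62 and 77, 512 and 432, 41 and 14, and 108. Limma on FPKM gave 380 lower genes between the doses. Leaving out both libraries that stand apart gave 3677 and 3721, 3125 and 3147, 3176 and 2929, and 4075, and voom with quality weights 3751 and 3765, 2965 and 3148, 2797 and 2767, and 3993. Upper-quartile factors moved the share of higher genes at 50 µM from 45.6% to 51%.

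Leaving out 1 library at a time gave 47 to 2382 higher and 43 to 2357 lower genes at 50 µM, 598 to 1966 and 457 to 1890 at 100 µM, 31 to 1823 and 12 to 1738 between the doses, and 84 to 1897 at both doses. Lists past the threshold numbered 11 to 13, 12 to 15 and 15 to 19. With an estimated correlation they numbered 0 in camera, against 13 in fry, then 3 and 5; fry gave 12 and an adjusted p under 0.01 gave 12 between the doses.

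Other list calls were gained as follows, with camera adjusted p. At 50 µM these were YAP/TEAD targets with upper-quartile factors (0.047), no filter (0.0356), voom weights (0.0254) or both libraries that stand apart left out (0.0448). Leaving out both also added immediate early genes (0.0377) and NF-kB genes (median 0.44, 0.00658) there. At 100 µM AhR targets passed with no filter (0.0216), with 1 CPM in 3 libraries (0.0485), with voom weights (0.0402) and with both left out (4.87e-07), and the integrated stress response with no filter (0.0441). Between the doses ribosomal proteins were lower with both left out (4.51e-11) and with voom weights (2.52e-10). Calls were also lost with both left out and with voom weights, given in that order. At 50 µM these were glycolysis (0.214, 0.271) and G2/M (0.214, 0.112). Between the doses they were heat shock (0.369, 0.285), integrated stress response (0.206, 0.0928), G2/M (0.351, 0.285) and TGF-beta targets (0.285 in each). So were NF-kB (0.55, 0.285) and fibroblast markers (0.527, 0.558). Ribosomal proteins at 100 µM lost the call with both left out (0.107).

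The log2 fold change of IGFBP3 at 50 µM ranged from 0.70 to 0.94 with 1 library left out and passed the threshold with only the 2 groups fitted (0.82, edgeR adjusted p = 0.00487) and without both libraries that stand apart (0.94, edgeR adjusted p = 9.61e-08). At 100 µM it ranged from 2.65 to 4.73. Between the doses it ranged from 1.81 to 3.91, and the call was lost with no filter (3.48, edgeR adjusted p = 0.0819), with only the 2 groups fitted (3.49, 0.0822), against 1.5-fold (3.48, 0.371) and on FPKM (2.59, limma adjusted p = 0.0508).

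Replicate numbers gave no sign of pairing: of 9 pairs with the same number 1 correlated above 0.1 (-0.464 to 0.276), and 0 libraries correlated best with their own number. The deviations were taken from group means that include the libraries that stand apart, which correlated at 0.533. Pairing can therefore not be excluded. With the replicate block the counts were 199 and 228, 893 and 779, 81 and 28, and 299 at both doses, and IGFBP3 between the doses was 2.97 (edgeR adjusted p = 0.0999).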

Other observations

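All tests on the hallmark gene sets in this part were chosen only after the result was seen.

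In the hallmark sets that the authors' table assigns to each gene, 3 of 50 sets passed camera at 50 µM, 17 at 100 µM and 32 between the doses, of which 0, 4 and 17 passed with an estimated correlation. At 50 µM these were cholesterol homeostasis, with 18 of 69 genes higher and 5 lower (camera adjusted p = 6.6e-05, adjusted p = 0.637 with an estimated correlation), bile acid metabolism (13 of 80 higher, 3 lower; 0.0121, then 0.666, and 0.0751 without both libraries that stand apart) and, lower, the mitotic spindle (10 of 195 higher, 27 lower; 0.0447, then 0.754). At 100 µM the set of coagulation genes, which encode clotting factors and their proteases, was higher: 35 of 96 rose and 5 fell (median 0.29, camera adjusted p = 2.19e-05, adjusted p = 0.0157 with an estimated correlation). Hypoxia genes had 70 of 168 higher and 6 lower (camera adjusted p = 6.2e-16, adjusted p = 0.0274 with an estimated correlation). At 50 µM that set did not pass, with 21 higher and 18 lower (median 0.014, camera adjusted p = 0.718), unlike the shorter list of HIF targets, and the test's direction was down without both libraries that stand apart (0.853).

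Between the doses the set of TNF signalling through NF-kB had 26 of 179 genes higher and 1 lower (median 0.32, camera adjusted p = 1.9e-11, adjusted p = 0.00221 with an estimated correlation), and without both libraries that stand apart its median was 0.3 (camera adjusted p = 2.94e-09). The shorter NF-kB and inflammatory list of the report lost its call there (median 0.064). Inflammatory response genes had 15 of 132 higher and 1 lower (median 0.24, camera adjusted p = 2.76e-07, adjusted p = 0.00221 with an estimated correlation), and complement genes 9 of 152 higher and 2 lower (camera adjusted p = 4.75e-05, adjusted p = 0.0035 with an estimated correlation). Against control the TNF set had medians of -0.1 at 50 µM and 0.211 at 100 µM (camera adjusted p = 0.164 and 0.0175). Inflammatory response genes had -0.101 and 0.119 (0.281 and 0.0739), and complement genes -0.0662 and 0.0888 (0.718 and 0.0431). None of these sets passed against control with an estimated correlation. Part of the difference between the doses thus lay below the control at 50 µM. MYC targets were lower, 27 of 200 in the first set with 2 higher and 9 of 58 in the second (adjusted p = 0.025 and adjusted p = 0.0208 with an estimated correlation).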
